A study of Rattus norvegicus with 18 samples.

How the data were processed

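Total RNA from adrenal glands of WKY, SHR and SHRSP rats aged 3 and 6 weeks was measured on 18 one-colour Agilent arrays with 44254 spots each, 42877 of them not controls. Per the labels, the glands were kept in an RNA preservative, RNA was extracted with a column kit, and labelling started from an oligo-dT primer and 200 ng of RNA with the Cy3 dye, so signals reflect transcripts with a poly(A) tail. Each group of strain and age held 3 samples that the labels call biological replicates. Per the file headers, the spots were read with Agilent Feature Extraction 10.5.1.1, as also stated in the submitters' processing notes. The deposited unit is the processed signal intensity on a linear scale. Per the file headers, it was corrected for spatial trends within the array, without subtraction of a local background, low values were replaced by a surrogate, and arrays were not normalized against each other. The series table deposited by the authors held the same intensities at every spot, with a difference of 0, and gave identical results. The header names rn4 as the assembly of the probe annotation, and the part of the gene under a probe (exon or UTR) was not given in the sources used here.

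Intensities were taken as log2 of the processed signal minus the 75th percentile of each array. Control spots and spots that the scanner software marked as non-uniform or population outliers were left out, and repeated spots of a probe were averaged on the log2 scale. A gene was represented by the probe with the highest mean over the 18 arrays, from 30367 probes with 26583 gene names. Genes were kept where the signal was well above background on all 3 arrays of at least 1 of the 6 groups, which left 20835, and 180 of them lacked a value on an array. Gene names were updated through accessions in a RefSeq gene table where it listed them, which it did for 17328 probes, and kept as in the files for 10407 others that were not matched. Of the tested names, 12980 were gene symbols in the files and 7855 identifiers.

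Because the arrays were not normalized by the authors, the percentile scaling fixes the level against which a gene is called higher or lower, and a fold is relative to it. Where a gene was not well above background on any array of a group, the fold is a bound. The bright group's mean log2 value was set against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal, and is given as at least that fold.

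One linear model of 6 group means was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 12 residual degrees of freedom and 2.12 prior ones. The design gave 9 pairwise comparisons, 3 between strains at each age and 1 between ages in each strain, and 3 comparisons of age changes between strains. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in each comparison, with no threshold on the fold. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

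Before the data were examined, 29 gene lists were fixed, and the 28 with at least 5 measured members were tested. They covered steroid hormone synthesis, zona glomerulosa, cholesterol, chromaffin cells, hormone inactivation, renin-angiotensin and ion transport, genes linked to SHR or SHRSP by literature, glucocorticoid response, immediate early genes, heat shock, cell cycle, growth and imprinting, fatty acids, mitochondria, glutathione, circadian clock, interferon, antigen presentation, and markers of other cell types and tissues. The list of sex chromosome genes had 1 measured member and was not tested. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, and with fry. Of 336 pairs of a list and a comparison, camera called 112 with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.0595. The median, the mean and the direction of camera had the same sign in each called pair. Camera's estimate treats genes of a list that vary together between replicates as fewer independent genes.

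Genes were named by a rule fixed before the data were examined. Among called genes with a symbol in the files and no overlap between the arrays of the groups, it takes the 5 largest rises and 5 largest falls of each pairwise comparison, the 3 largest each way of each comparison of age changes, and the 6 highest and 6 lowest of those called the same way in all 4 comparisons with WKY. It adds up to 4 members of each list with the smallest adjusted p in a comparison, with their values in the others, and, whatever their result, Cyp11b1, Cyp11b2, Cyp21a1, Star, Th, Dbh, Pnmt, Cd36, Ephx2 and Gstm1. Lcn2 and Slc22a6 were named after their values were seen. Some genes that this rule takes are not reported here.

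The arrays lay on 5 slides scanned on 3 days. Slide 1 held replicate 1 of WKY, SHR and SHRSP at 3 weeks and of WKY at 6 weeks. Slide 2 held replicate 2 of WKY and SHR at 3 weeks and replicate 1 of SHR and SHRSP at 6 weeks, slide 3 replicate 2 of SHRSP at both ages, slide 4 replicate 3 of the 3 strains at 3 weeks and of WKY at 6 weeks, and slide 5 replicate 2 of WKY and SHR and replicate 3 of SHR and SHRSP at 6 weeks. Each comparison was therefore repeated with slide as a block and within each slide with both groups. Of the 112 list calls, 97 held with the block and 0 turned. Of the 83 in pairwise comparisons, 80 kept the median's sign within each such slide. These arrays made the calls, and some comparisons had 1 such slide.

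The fit was tested on simulated data for SHR against WKY at 3 weeks, with 20655 genes of which 200 were changed. It recovered 52.2% of the 67 genes changed by 1.5-fold, 70.1% of the 67 changed by 2-fold and 98.5% of the 66 changed by 4-fold, with 0 in the wrong direction, and called 9 unchanged genes. The alternatives were quantile normalization, normexp background correction with an offset of 50, no filter, a filter of well above background on all 18 arrays, all probes, the mean of a gene's probes, a block for the replicate number, a block for the slide, a trended robust prior, array weights, the groups compared alone, the authors' series table, and each array left out in turn. A fit without the 4 arrays of slide 5 was added after the data were seen.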

Results

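Transcript levels were measured in adrenal glands from rats of 3 strains, aged 3 or 6 weeks. The strains were WKY, a normotensive strain, SHR, the spontaneously hypertensive rat, and SHRSP, its stroke-prone relative. Each of the 6 groups of strain and age held 3 biological replicates, which gave 18 one-colour Cy3 arrays. Between 77.8% and 84.8% of the spots of an array lay well above background, no spot was saturated, and the 75th percentile of the processed signal ran from 2092 to 2602. After filtering, 20835 gene names were tested, 18326 of them well above background on all 18 arrays. The number of arrays limits the precision of each value, and the sex of the rats and the hour of collection were not given in the sources used here.

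Strain and age names below are those of the labels. All values are log2 differences with their standard errors from limma, with n = 3 arrays in each group, unless a fold is given. For a gene list, counts are over its measured members, the value called slide-blocked is the median with slide as a block, and the last p is camera's with an estimated correlation. Each gene named for the size of its difference in a pairwise comparison had no overlap between the 3 arrays of one group and the 3 of the other. The first 3 principal components held 27.8%, 22.14% and 14.19% of the variance. Arrays of one group correlated with r of at least 0.987 across genes, which are not independent replicates.

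At 3 weeks, the largest rises in SHR over WKY were in Oxnad1, Kynu and Vom2r53, none of which was well above background on a WKY array. Oxnad1 was at least 49.3-fold higher (limma adjusted p = 1.94e-07), Kynu, the kynureninase of tryptophan breakdown, at least 91.2-fold higher, and Vom2r53, a vomeronasal receptor gene, at least 26.2-fold higher. Vegfb, a growth factor of the VEGF family, was at least 301-fold lower in SHR, where it was not well above background (adjusted p = 1.49e-13). Apln, which encodes the apelin peptide, differed by -4.27 ± 0.27, Gfra1, a receptor for the neurotrophic factor GDNF, by -4.13 ± 0.29, and Scn10a, a sodium channel of sensory neurons, by -3.99 ± 0.17. The probes of Oxnad1, Kynu and Vegfb lay on the rn4 assembly at chromosome 16, 7574653 to 7574712, chromosome 3, 24195524 to 24195583, and chromosome 1, 209657830 to 209657889.

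The list of chromaffin and catecholamine genes was called higher in SHR at 3 weeks, where 11 of 32 members were higher and 1 lower (median 0.46, 0.46 slide-blocked and 0.30 to 0.68 within slides, camera adjusted p = 6.82e-05, adjusted p = 0.598 with estimated correlation). Hand2, a transcription factor of sympathoadrenal cells, rose by 1.15 ± 0.15, Gch1, which makes the cofactor of tyrosine hydroxylase, by 1.76 ± 0.27, and the secretory granule gene Scg2 by 0.56 ± 0.09. Th itself was at 0.33 ± 0.13 and Pnmt, which forms adrenaline, at 0.13 ± 0.12, neither past the threshold. In the cholesterol list 13 of 29 members were higher and 0 lower (median 0.30, 0.27 to 0.40 within slides, camera adjusted p = 7.49e-05, adjusted p = 0.598 with estimated correlation). Hsd17b7 was at 1.43 ± 0.18 and Insig1 at 1.54 ± 0.21. The count was 15 higher and 0 lower adjusted over the list alone. The steroid hormone list was not called (camera adjusted p = 0.657), although Star, which carries cholesterol into mitochondria, was higher by 0.57 ± 0.08 and Srd5a1, a steroid reductase, differed by -0.63 ± 0.16. Cyp11b2, the aldosterone synthase, was at 0.13 ± 0.13.

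Immediate early genes were called higher as a list in SHR at 3 weeks, where 11 of 27 members were higher and 0 lower (median 0.58, 0.52 to 0.62 within slides, camera adjusted p = 0.00017, adjusted p = 0.622 with estimated correlation). Atf3 was at 1.71 ± 0.22 and Ier3 at 1.47 ± 0.25. Markers of fat were called higher too. In the adipose list 5 of 24 members were higher and 0 lower (median 0.63, 0.43 to 0.78 within slides, camera adjusted p = 0.0013, adjusted p = 0.652 with estimated correlation). Elovl3 was at 1.42 ± 0.25 and Lpl at 1.68 ± 0.35. The kidney and liver list, with a median of 0.48 and -0.05 to 2.59 within slides, was not called (camera adjusted p = 0.168) except without SHR replicate 1 or 3 (adjusted p = 0.011 and 0.0413). In the fatty acid list, called higher beside these fat markers, 6 of 35 members were higher and 0 lower (median 0.21, 0.14 to 0.30 within slides, camera adjusted p = 0.00125, adjusted p = 0.628 with estimated correlation). The endothelial list was called higher (6 of 23 higher, 1 lower, median 0.23, 0.16 to 0.25 within slides, camera adjusted p = 0.00841, adjusted p = 0.598 with estimated correlation). The renin-angiotensin and ion transport list was called higher (9 of 41 higher, 2 lower, median 0.20, 0.09 to 0.27 within slides, camera adjusted p = 0.01, adjusted p = 0.598 with estimated correlation). In it the neuronal nitric oxide synthase Nos1 was at 1.44 ± 0.25. Among glucocorticoid-responsive genes, 6 of 18 members were higher and 0 lower (median 0.26, 0.16 to 0.34 within slides, camera adjusted p = 0.0482, lost with slide as a block at adjusted p = 0.0689, adjusted p = 0.652 with estimated correlation). Fkbp5 was at 1.12 ± 0.11 and Glul at 1.26 ± 0.21. The inactivation list was called higher (4 of 10 higher, 0 lower, median 0.39, 0.30 to 0.59 within slides, camera adjusted p = 0.02, adjusted p = 0.598 with estimated correlation). So were the glutathione list (5 of 49 higher, 4 lower, median 0.14, 0.10 to 0.15 within slides, camera adjusted p = 0.0482, adjusted p = 0.693 with estimated correlation) and the heat shock list (8 of 31 higher, 1 lower, median 0.09, 0.04 to 0.15 within slides, camera adjusted p = 0.0482, adjusted p = 0.652 with estimated correlation). The Schwann cell list was called higher too (1 of 19 higher, 0 lower, median 0.31, 0.03 to 0.89 within slides, camera adjusted p = 0.0482, lost with slide as a block at adjusted p = 0.0712, adjusted p = 0.723 with estimated correlation). Its member past the threshold was the neurofilament gene Nefh, at 1.41 ± 0.15.

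In limma, 3797 genes differed between SHR and WKY at 3 weeks, 1879 higher and 1918 lower in SHR, and 733 of them by at least 2-fold. With slide as a block the count was 5302, and on the 3 slides that held both groups at least 99.9% of the called genes had the same sign, though these arrays are part of the calls.

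In SHRSP at 3 weeks, Vom2r53 was at least 82.6-fold higher than in WKY, Oxnad1 at least 68.9-fold higher and Kynu at least 45.1-fold higher, with none of them well above background in WKY. Acox2, a peroxisomal oxidase, was at least 5.9-fold higher, and Myo16, an unconventional myosin, rose by 3.93 ± 0.52. Serpinc1, which encodes antithrombin, was lower by a log2 difference of -8.42 ± 0.79 with 2 of 3 SHRSP arrays well above background (limma adjusted p = 4.71e-06). Agtrap, an angiotensin receptor-associated protein, was at -5.34 ± 0.16, and Ephx2, the soluble epoxide hydrolase, at -2.83 ± 0.30. Apln, Scn10a and the fetal plasma protein gene Afp were at -4.70 ± 0.27, -4.48 ± 0.17 and -4.45 ± 0.87.

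The chromaffin list was again called higher, with Chgb at 0.73 ± 0.10, Scg2 at 0.62 ± 0.09, Th at 0.71 ± 0.13 and Pnmt at 0.73 ± 0.12, while Ddc, the decarboxylase between Th and Dbh, was lower at -0.61 ± 0.08. In that list 13 of 32 members were higher and 1 lower (median 0.25, 0.30 slide-blocked and 0.25 to 0.28 within slides, camera adjusted p = 0.0396, adjusted p = 0.935 with estimated correlation). In the cholesterol list 12 of 29 members were higher and 1 lower (median 0.30, 0.36 slide-blocked and 0.30 to 0.38 within slides, camera adjusted p = 0.000893, adjusted p = 0.935 with estimated correlation). Stard4, a cholesterol transfer protein, was at 2.56 ± 0.11 and Acat2 at 1.91 ± 0.20. Star was higher by 0.98 ± 0.08, Cyp11b2 by 0.53 ± 0.13 and Cyp11b1, the corticosterone-forming hydroxylase, by 0.30 ± 0.08. Nr0b1, a repressor of steroid gene transcription, was at -1.84 ± 0.21.

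Interferon-response genes were lower as a group in SHRSP than in WKY at 3 weeks, where 1 of 36 members were higher and 9 lower (median -0.39, -0.39 slide-blocked and -0.81 to 0.11 within slides, camera adjusted p = 0.000893, adjusted p = 0.935 with estimated correlation). Ifi44l stood at -2.69 ± 0.13 and Oasl at -1.64 ± 0.21, while Isg20 was higher at 0.89 ± 0.12. The median lay above 0 on 1 of the 2 slides that held both groups. The macrophage list was called higher, where 10 of 22 members were higher and 1 lower (median 0.44, 0.47 slide-blocked and 0.27 to 0.59 within slides, camera adjusted p = 0.045, lost with that block at adjusted p = 0.0736, adjusted p = 0.935 with estimated correlation). Cd68 was at 0.65 ± 0.14 and Cd163 at 0.995 ± 0.23. Endothelial genes were called higher (11 of 23 higher, 1 lower, median 0.32, 0.32 slide-blocked and 0.18 to 0.41 within slides, camera adjusted p = 0.0222, adjusted p = 0.935 with estimated correlation). Fatty acid genes were called higher (13 of 35 higher, 2 lower, median 0.25, 0.26 slide-blocked and 0.16 to 0.28 within slides, camera adjusted p = 0.0113, adjusted p = 0.935 with estimated correlation). Adipose markers were called higher as a list (6 of 24 higher, 0 lower, median 0.73, 0.63 slide-blocked and 0.45 to 0.62 within slides, camera adjusted p = 0.0222, lost with that block at adjusted p = 0.0799, adjusted p = 0.935 with estimated correlation). In the respiratory chain list, called higher, 3 of 65 members were higher and 0 lower, or 0 higher and 0 lower adjusted over the list alone (median 0.16, 0.11 slide-blocked and 0.10 to 0.10 within slides, camera adjusted p = 0.045, lost with that block at adjusted p = 0.0799, adjusted p = 0.994 with estimated correlation).

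At 3 weeks 5462 genes differed between SHRSP and WKY in limma, 3077 higher and 2385 lower, 1118 of them by at least 2-fold. Quantile normalization turned this majority, with 2589 higher and 2673 lower. The count was 6453 with slide as a block, and 99.9% or more of the calls had the same sign on each of the 2 slides that held both groups.

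At 6 weeks Oxnad1 was at least 106-fold higher in SHR than in WKY, Vom2r53 at least 20.1-fold higher, and Kynu higher by 6.18 ± 0.21 with 1 of 3 WKY arrays well above background. Serpinc1 was at -9.06 ± 0.79, Agtrap at -5.15 ± 0.16 (limma adjusted p = 7.95e-11) and Prss35, a serine protease gene, at -4.76 ± 0.34. Ephx2 was at least 13.3-fold lower in SHR, where no array had it well above background. Its probe lay at chromosome 15, 45535737 to 45538220 on rn4, and that of Agtrap at chromosome 5, 165154364 to 165154423. The fatty acid transporter Cd36 was at -1.56 ± 0.15. At 3 weeks its SHR levels (4.24 to 4.69) overlapped WKY (4.49 to 4.64).

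The cell cycle list was lower in SHR at 6 weeks, where 1 of 43 members were higher and 32 lower (median -0.997, -0.93 slide-blocked and -0.83 within slide, camera adjusted p = 6.77e-13, adjusted p = 0.825 with estimated correlation). Aurka, a mitotic kinase, was at -0.99 ± 0.12, Ccnb1, a mitotic cyclin, at -1.63 ± 0.23 and the replication helicase gene Mcm2 at -1.02 ± 0.15, while Mcm7 was higher at 0.69 ± 0.08. Chaperone genes were higher, in a list where 14 of 31 members were higher and 0 lower (median 0.32, 0.36 slide-blocked and 0.30 within slide, camera adjusted p = 0.000181, adjusted p = 0.825 with estimated correlation). Dnaja1 was at 1.30 ± 0.13 and Hsph1 at 1.31 ± 0.15. Of the chromaffin list, 15 of 32 members were higher and 1 lower (median 0.55, 0.54 slide-blocked and 0.45 within slide, camera adjusted p = 0.000419, adjusted p = 0.825 with estimated correlation). Pnmt stood at 0.96 ± 0.12, Th at 0.87 ± 0.13 and Dbh, which forms noradrenaline, at 0.62 ± 0.17. In the antigen presentation list 12 of 35 members were higher and 2 lower (median 0.24, 0.34 slide-blocked and 0.47 within slide, camera adjusted p = 0.0037, adjusted p = 0.825 with estimated correlation). The class II gene RT1-Db1 was at 1.71 ± 0.19 and its activator Ciita at 1.68 ± 0.20.

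The aldosterone synthase Cyp11b2 was higher in SHR at 6 weeks by 1.13 ± 0.13, Cyp11b1 by 0.74 ± 0.08 and Star by 0.79 ± 0.08, while Nr0b1 was at -2.47 ± 0.21. In the steroid list 9 of 23 members were higher and 2 lower, or 10 higher and 2 lower adjusted over the list alone, without a call for the list (camera adjusted p = 0.0649), which was called with slide as a block (adjusted p = 0.0354). Cyp21a1, the hydroxylase gene, was not past the threshold in any comparison. Haemoglobin and red cell genes were lower, in a list where 0 of 8 members were higher and 4 lower (median -0.44, -0.40 slide-blocked and -0.37 within slide, camera adjusted p = 0.00623, adjusted p = 0.825 with estimated correlation). Adipose markers were called lower as a list (0 of 24 higher, 2 lower, median -0.44, -0.54 slide-blocked and -0.10 within slide, camera adjusted p = 0.011, adjusted p = 0.825 with estimated correlation). Ucp1, the uncoupling protein of brown fat, was at -3.28 ± 0.78.

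In limma 6080 genes differed between SHR and WKY at 6 weeks, 3378 higher and 2702 lower, 1150 of them by at least 2-fold. With quantile normalization 2666 were higher and 2773 lower, and with these 6 arrays alone 1266 and 1364. The count was 7323 with slide as a block. Without slide 5, left out after the data were seen, it was 3470, with 1 SHR array left at 6 weeks.

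In SHRSP at 6 weeks, Oxnad1 was at least 86.1-fold higher than in WKY and Vom2r53 at least 21.7-fold higher, Kynu rose by 5.36 ± 0.21 with 1 of 3 WKY arrays well above background, and Ass1, the argininosuccinate synthase, by 3.66 ± 0.38. Vegfb was at least 368-fold lower and not well above background in SHRSP (limma adjusted p = 1.05e-13). The kinase gene Sbk2 was at least 24.8-fold lower, Scn10a was at -5.06 ± 0.17 and Prss35 at -5.60 ± 0.34. Ephx2 was at -0.10 ± 0.30, not past the threshold, and Cd36 at -1.24 ± 0.15.

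Chromaffin genes were higher, in a list where 13 of 32 members were higher and 0 lower (median 0.67, 0.69 slide-blocked and 0.48 within slide, camera adjusted p = 2.08e-06, adjusted p = 0.471 with estimated correlation). Pnmt was at 1.02 ± 0.12, Th at 0.95 ± 0.13 and Hand2 at 1.25 ± 0.15. The zona glomerulosa list, which marks the aldosterone-producing layer, was higher as a group. In it 8 of 21 members were higher and 3 lower (median 0.32, 0.33 slide-blocked and 0.30 within slide, camera adjusted p = 0.0283, adjusted p = 0.471 with estimated correlation). Cyp11b2 was at 0.88 ± 0.13 and Hsd3b2 at 1.24 ± 0.18, while the calcium channel gene Cacna1d was lower at -0.67 ± 0.10. Imprinted and growth genes were higher, in a list where 5 of 13 members were higher and 0 lower (median 0.13, 0.19 slide-blocked and 0.15 within slide, camera adjusted p = 0.0181, adjusted p = 0.471 with estimated correlation). Igf1 was at 1.52 ± 0.24 and Cdkn1c at 1.11 ± 0.15. Nr0b1 was at -2.62 ± 0.21.

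Immediate early genes were lower in SHRSP at 6 weeks, where 2 of 27 members were higher and 15 lower (median -1.06, -0.94 slide-blocked and -1.38 within slide, camera adjusted p = 5.61e-05, adjusted p = 0.642 with estimated correlation). Fos was at -3.93 ± 0.47, well above background on 2 of 3 SHRSP arrays, and Arc at -2.23 ± 0.17. In the cell cycle list 1 of 43 members were higher and 21 lower (median -0.58, -0.67 slide-blocked and -0.65 within slide, camera adjusted p = 6.56e-06, adjusted p = 0.854 with estimated correlation). Aurka was at -1.60 ± 0.12. Lymphocyte genes were lower, in a list where 0 of 23 members were higher and 7 lower (median -0.48, -0.45 slide-blocked and -0.38 within slide, camera adjusted p = 0.00678, adjusted p = 0.471 with estimated correlation). The T cell receptor gene Cd3g was at -1.72 ± 0.22 and Cd247 at -1.31 ± 0.19. Glucocorticoid-responsive genes were called lower (1 of 18 higher, 6 lower, median -0.32, -0.32 slide-blocked and -0.46 within slide, camera adjusted p = 0.0193, lost with that block at adjusted p = 0.0515, adjusted p = 0.749 with estimated correlation). The blood list was called lower (0 of 8 higher, 3 lower, median -0.39, -0.50 slide-blocked and -0.55 within slide, camera adjusted p = 0.0181, adjusted p = 0.788 with estimated correlation). Among the glucocorticoid genes, Dusp1 was at -2.001 ± 0.29 and Ddit4 at -2.54 ± 0.40, while Glul was higher at 0.93 ± 0.21.

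The limma count at 6 weeks was 4985 genes between SHRSP and WKY, 2311 higher and 2674 lower, with 1063 of at least 2-fold. Quantile normalization gave 2632 higher and 2413 lower, the opposite majority. With slide as a block it was 6122, and 2377 when only these 6 arrays were fitted, and 99.9% of the calls had the same sign on the 1 slide that held both groups.

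**Figure D1:**
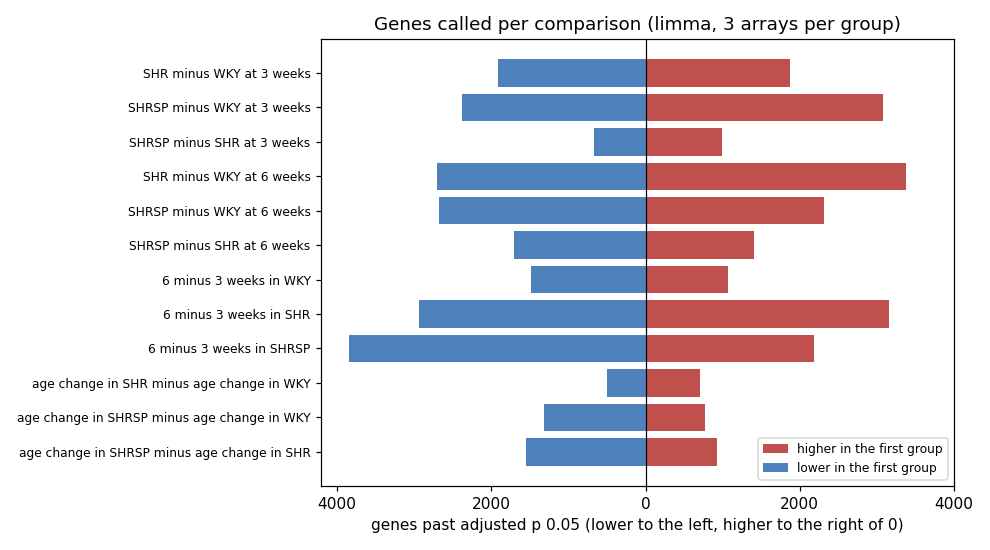
Genes called by limma at an adjusted p under 0.05 in the 12 comparisons, with bars from 0 for genes higher and lower in the first-named group. The age comparisons within SHR and SHRSP called 6096 and 6034 genes, against 2566 in WKY.

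SHR and SHRSP shared many of their differences from WKY. Across both ages, 1230 genes were called the same way in all 4 comparisons, 640 higher and 590 lower. Besides Oxnad1, Kynu and Vom2r53, these included Acox2, Tmem163 and Myo16 among the highest, with Tmem163, a zinc transporter gene, at 4.41 ± 0.29 in SHRSP at 6 weeks and at 2.37 ± 0.29 in SHR at 3 weeks, where 2 of 3 WKY arrays measured it. Among the lowest, Apln lay between -4.04 ± 0.27 and -4.70 ± 0.27, Prss35 between -3.04 ± 0.34 and -5.60 ± 0.34, and Scn10a between -3.51 ± 0.17 and -5.06 ± 0.17. From a list of genes that literature links to these strains, Folr1, a folate receptor, ran from 1.31 ± 0.16 to 2.84 ± 0.16, and Endog, a mitochondrial nuclease, from -1.99 ± 0.13 to -1.70 ± 0.13. That list as a whole was not called in any of the 4 comparisons, and Gstm1, a member known to be low in SHRSP, was not called in any comparison.

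At 3 weeks 2647 genes were called the same way in SHR and SHRSP and 34 in opposite directions, and at 6 weeks 3005 and 109. Independent lists of these sizes would share 277.5 higher and 219.6 lower genes at 3 weeks and 374.7 and 346.8 at 6 weeks. Unchanged groups simulated with shared WKY arrays shared 0, but with few calls this sets no baseline. The correlation of fold changes across genes was 0.701 and 0.684 at 3 and 6 weeks (simulated 0.495 and 0.5). The covariance was 0.190 and 0.2055 (simulated 0.0318 and 0.0326). Part of the excess may come from the shared WKY arrays, since 3 arrays cannot be split, and genes are not independent replicates.

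**Figure D2:**
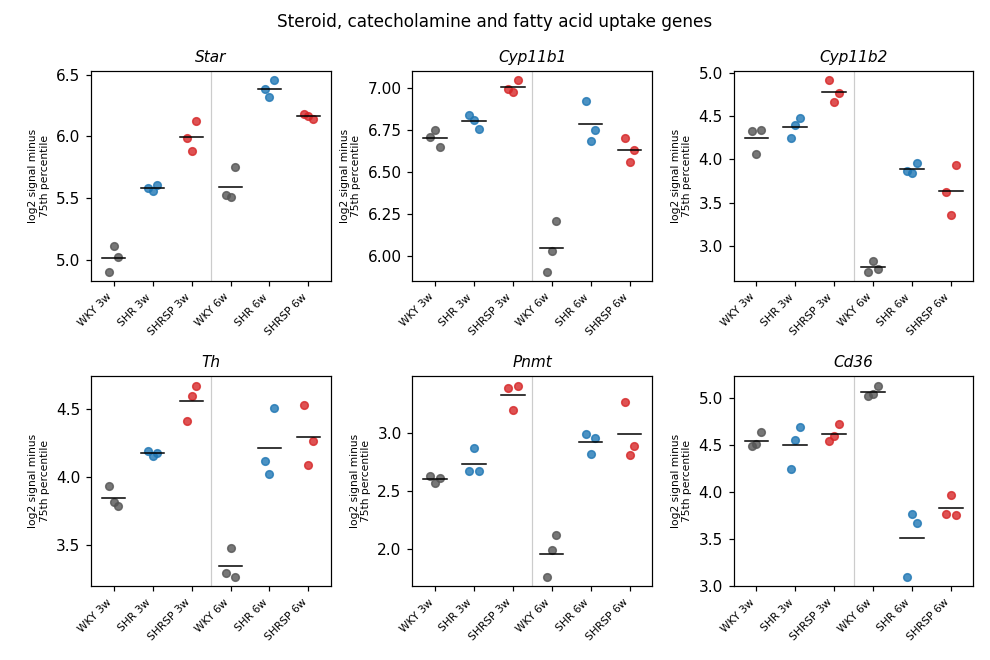
Log2 signal of Star, Cyp11b1, Cyp11b2, Th, Pnmt and Cd36 relative to the 75th percentile of each array, with a point for each array and a bar for the mean of each of the 6 groups of 3. At 6 weeks the means of Cyp11b2, Th and Pnmt lay higher in SHR and SHRSP than in WKY, and that of Cd36 lower.

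Between the arrays labelled SHRSP and SHR at 3 weeks, Vegfb was at least 352-fold higher in SHRSP (limma adjusted p = 1.09e-13), and not well above background in SHR. Zfp597, a zinc finger gene, rose by 3.12 ± 0.08. Agtrap was lower in SHRSP at -4.86 ± 0.16, Ephx2 at -3.35 ± 0.30, and Serpinc1 at -8.47 ± 0.79 with 2 of 3 SHRSP arrays well above background. Stard4 was higher at 2.31 ± 0.11.

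The interferon list was lower in SHRSP than in SHR at 3 weeks, where 0 of 36 members were higher and 5 lower, or 0 higher and 11 lower adjusted over the list alone (median -0.48, -0.47 slide-blocked and -0.97 to -0.16 within slides, camera adjusted p = 2.28e-08, adjusted p = 0.915 with estimated correlation). Eif2ak2, an RNA-sensing kinase, was at -1.13 ± 0.13 and Oasl at -1.56 ± 0.21. Immediate early genes were lower as a list (0 of 27 higher, 2 lower, median -0.48, -0.46 slide-blocked and -0.51 to -0.44 within slides, camera adjusted p = 1.53e-06, adjusted p = 0.915 with estimated correlation). Atf3 was at -1.79 ± 0.22. Cell cycle genes were called higher as a list, where 5 of 43 members were higher and 0 lower (median 0.47, 0.28 slide-blocked and 0.00 to 0.61 within slides, camera adjusted p = 1.64e-06, adjusted p = 0.915 with estimated correlation). Ccne1 was at 0.58 ± 0.16. Schwann cell genes were lower as a list (median -0.43, -0.50 slide-blocked and -0.83 to -0.16 within slides, camera adjusted p = 0.000203, adjusted p = 0.915 with estimated correlation). None of its 19 members passed the threshold over all genes. Star was higher at 0.41 ± 0.08 and Pnmt at 0.59 ± 0.12.

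In limma 1654 genes differed, 986 higher and 668 lower in SHRSP, 278 of them by at least 2-fold, and 2273 with slide as a block. The count fell to 892 without SHR replicate 2, 958 without SHRSP replicate 2, 1046 without SHRSP replicate 3, and 1019 with these 6 arrays alone. The direction rests on the labels, whose largest differences changed sign by 6 weeks, as given below.

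At 6 weeks the arrays labelled SHRSP had Serpinc1 higher than SHR by 9.63 ± 0.79, Agtrap by 5.35 ± 0.16 (limma adjusted p = 4.33e-11) and Uts2, the vasoactive peptide urotensin, by 4.08 ± 0.41. Ephx2 was at least 12.4-fold higher. Vegfb was at least 406-fold lower and not well above background in SHRSP. The chaperone gene Hspa1b was at -5.41 ± 0.50 and the nuclear receptor gene Nr4a3 at -4.27 ± 0.87.

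Heat shock genes were lower as a group in SHRSP than in SHR at 6 weeks, where 1 of 31 members were higher and 15 lower (median -0.35, -0.36 slide-blocked and -0.33 to -0.32 within slides, camera adjusted p = 8.92e-06, adjusted p = 0.833 with estimated correlation). Dnaja1 was at -1.42 ± 0.13 and Atf4 at -1.15 ± 0.15. In the cholesterol list 0 of 29 members were higher and 9 lower (median -0.23, -0.26 slide-blocked and -0.37 to -0.20 within slides, camera adjusted p = 0.000461, adjusted p = 0.84 with estimated correlation). Stard4 was at -2.86 ± 0.11 and Insig1 at -2.28 ± 0.21. Immediate early genes were called lower (0 of 27 higher, 10 lower, median -0.55, -0.50 slide-blocked and -0.77 to -0.35 within slides, camera adjusted p = 0.00361, adjusted p = 0.84 with estimated correlation). Glucocorticoid-responsive genes were called lower as a list (0 of 18 higher, 7 lower, median -0.38, -0.28 slide-blocked and -0.54 to -0.30 within slides, camera adjusted p = 0.00983, adjusted p = 0.84 with estimated correlation), and Fkbp5 was at -1.19 ± 0.11. Antigen presentation genes were called lower as a list, where 0 of 35 members were higher and 5 lower (median -0.19, -0.19 slide-blocked and -0.22 to -0.01 within slides, camera adjusted p = 0.00506, adjusted p = 0.84 with estimated correlation), and Ciita was at -1.84 ± 0.20. Cell cycle genes were called higher (4 of 43 higher, 1 lower, median 0.32, 0.08 slide-blocked and 0.03 to 0.33 within slides, camera adjusted p = 3.07e-05, adjusted p = 0.84 with estimated correlation). Mcm2 was at 0.73 ± 0.15. Adipose markers were called higher as a list (median 0.33, 0.43 slide-blocked and 0.47 to 0.75 within slides, camera adjusted p = 0.0172, adjusted p = 0.84 with estimated correlation). None of its 24 members passed the threshold. Star, Cyp11b1, Cyp11b2, Th, Pnmt and Cd36 did not pass it, with Star at -0.22 ± 0.08 and Cyp11b2 at -0.25 ± 0.13.

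The limma count was 3118, 1405 higher and 1713 lower in SHRSP (1631 and 1267 with quantile normalization), with 513 of at least 2-fold, and 3953 with slide as a block. The median of all genes was -0.11, and with quantile normalization, where it was -0.02, the share of higher calls moved from 45.1% to 56.3%. Fitted on these 6 arrays alone the count was 1233, and without slide 5, left out after the data were seen, 1364.

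Several of the largest differences between SHR and SHRSP changed sign between the ages. Vegfb was not well above background in SHR at 3 weeks and in SHRSP at 6 weeks, and lay well above it on all 3 arrays of each other group. Agtrap, Ephx2, Serpinc1 and Stard4 crossed in the same manner, with Agtrap going from -4.86 ± 0.16 at 3 weeks to 5.35 ± 0.16 at 6 weeks. Of the genes called between SHRSP and SHR at both ages, 345 of 733 had opposite signs at any fold, 69 of 100 at 2-fold or more, and 22 of 25 at 4-fold or more at both ages. With slide as a block the last count was 19 of 23. At 4-fold, 2 of 59 genes had opposite signs for SHR against WKY and 0 of 68 for SHRSP. The correlation of fold changes between the ages, across genes, was -0.194 for SHRSP against SHR, 0.494 for SHR against WKY and 0.473 for SHRSP against WKY. Each comparison below that follows SHR or SHRSP from one age to the other carries this crossing, and the comparison within WKY does not. Set across the labels after the data were seen, SHRSP at 6 weeks against SHR at 3 weeks called 5835 genes and SHR at 6 weeks against SHRSP at 3 weeks 5025, against 6096 in SHR and 6034 in SHRSP as labelled.

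**Figure D3:**
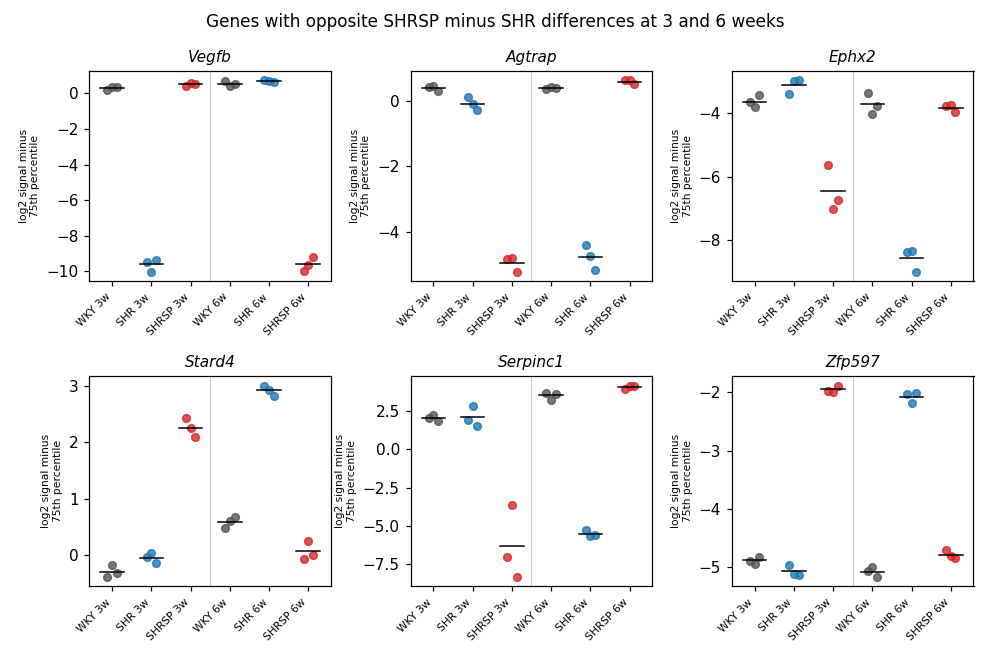
Log2 signal of Vegfb, Agtrap, Ephx2, Stard4, Serpinc1 and Zfp597 relative to the 75th percentile of each array, with a point for each array and a bar for each group mean. Arrays labelled SHR at 3 weeks lie with those labelled SHRSP at 6 weeks, and arrays labelled SHRSP at 3 weeks with those labelled SHR at 6 weeks.

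From 3 to 6 weeks in WKY, the largest fall was in Akr1c3, listed in the files as Akr1c18, an aldo-keto reductase of progesterone breakdown, at -9.72 ± 0.42 with 2 of 3 arrays well above background at 6 weeks (limma adjusted p = 2.65e-08). Its relative Akr1c14 fell by a log2 difference of -5.65 ± 0.32, and Cdh1, the E-cadherin gene, of -4.17 ± 0.51. The probe of Akr1c3 lay at chromosome 17, 77284120 to 77284179 on rn4. Slc9a3, a sodium-proton exchanger, rose by 6.49 ± 0.88 with 2 of 3 arrays well above background at 3 weeks.

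Cholesterol genes rose together in WKY. In the list 18 of 29 members rose and 0 fell (median 0.70, 0.67 slide-blocked and 0.69 to 0.94 within slides, camera adjusted p = 1.74e-12, adjusted p = 0.0595 with estimated correlation). Idi1 was at 1.74 ± 0.19 and Hsd17b7 at 1.30 ± 0.18. Matrix genes fell, in a list where 1 of 33 members rose and 17 fell (median -0.57, -0.56 slide-blocked and -0.84 to -0.50 within slides, camera adjusted p = 2.95e-10, adjusted p = 0.429 with estimated correlation). The collagen gene Col5a2 was at -0.999 ± 0.11 and the elastin gene Eln at -1.05 ± 0.20. Imprinted and fetal growth genes fell, in a list where 1 of 13 members rose and 8 fell (median -0.54, -0.51 slide-blocked and -0.58 to -0.41 within slides, camera adjusted p = 5.33e-05, adjusted p = 0.0595 with estimated correlation). H19 was at -2.52 ± 0.34, Igf2bp2 at -1.36 ± 0.13 and Cdkn1c at -1.39 ± 0.15. Cyp11b2 fell by a log2 difference of -1.49 ± 0.13 and Cyp11b1 of -0.65 ± 0.08, while Star rose by 0.58 ± 0.08. The steroid list was called lower (1 of 23 higher, 8 lower, median -0.03, 0.04 slide-blocked and -0.14 to -0.06 within slides, camera adjusted p = 0.0324, lost with that block at adjusted p = 0.495, adjusted p = 0.5 with estimated correlation), although its median was above 0 with slide as a block. The glomerulosa list was called lower (0 of 21 higher, 4 lower, median -0.20, -0.21 slide-blocked and -0.24 to -0.14 within slides, camera adjusted p = 0.0382, lost with that block at adjusted p = 0.105, adjusted p = 0.429 with estimated correlation). Th and Pnmt fell, at -0.50 ± 0.13 and -0.64 ± 0.12, and the chromaffin list was called lower (0 of 32 higher, 3 lower, median -0.25, -0.22 slide-blocked and -0.29 to -0.24 within slides, camera adjusted p = 0.0035, adjusted p = 0.5 with estimated correlation).

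Lymphocyte genes rose in WKY, in a list where 8 of 23 members rose and 0 fell (median 0.34, 0.26 slide-blocked and 0.14 to 0.53 within slides, camera adjusted p = 0.000329, adjusted p = 0.145 with estimated correlation). The granule gene Nkg7 was at 0.95 ± 0.12 and Gzma at 0.86 ± 0.12. Macrophage genes rose as a list (6 of 22 higher, 0 lower, median 0.23, 0.26 slide-blocked and 0.08 to 0.53 within slides, camera adjusted p = 0.00245, adjusted p = 0.526 with estimated correlation). Interferon genes rose as a list (4 of 36 higher, 0 lower, median 0.37, 0.32 slide-blocked and -0.09 to 0.68 within slides, camera adjusted p = 1.66e-05, adjusted p = 0.5 with estimated correlation). Antigen presentation genes rose as a list (4 of 35 higher, 1 lower, median 0.17, 0.19 slide-blocked and 0.19 to 0.35 within slides, camera adjusted p = 0.00245, adjusted p = 0.5 with estimated correlation). Immediate early genes did so too (7 of 27 higher, 1 lower, median 0.45, 0.46 slide-blocked and 0.14 to 0.50 within slides, camera adjusted p = 0.000616, adjusted p = 0.5 with estimated correlation). Glucocorticoid-responsive genes were called higher (5 of 18 higher, 0 lower, median 0.36, 0.32 slide-blocked and 0.09 to 0.47 within slides, camera adjusted p = 0.000616, adjusted p = 0.429 with estimated correlation), and so were fatty acid genes (8 of 35 higher, 1 lower, median 0.23, 0.20 slide-blocked and -0.05 to 0.47 within slides, camera adjusted p = 0.000725, adjusted p = 0.5 with estimated correlation). The metallothionein gene Mt1 rose by 1.08 ± 0.18 and the macrophage gene Fcgr3a by 1.57 ± 0.26. The blood list was called lower (0 of 8 higher, 2 lower, median -0.47, -0.39 slide-blocked and -0.66 to -0.08 within slides, camera adjusted p = 0.000616, adjusted p = 0.429 with estimated correlation). So was the Schwann cell list (0 of 19 higher, 4 lower, median -0.44, -0.37 slide-blocked and -0.69 to -0.24 within slides, camera adjusted p = 0.0245, lost with that block at adjusted p = 0.0543, adjusted p = 0.548 with estimated correlation). The mast cell and granulocyte list was called lower, though its 1 member past the threshold, Lcn2, rose (1 of 18 higher, 0 lower, median -0.33, -0.50 slide-blocked and -1.08 to -0.29 within slides, camera adjusted p = 0.0362, adjusted p = 0.539 with estimated correlation).

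In limma 2566 genes changed with age in WKY, 1074 up and 1492 down, 412 by at least 2-fold, and 3605 with slide as a block. The count fell to 1440 without the 3-week replicate 3, 1490 without replicate 1, 1558 without replicate 2, and 1108 with these 6 arrays alone.

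From 3 to 6 weeks in the arrays labelled SHR, Akr1c3 fell at least 549-fold to a level not well above background (limma adjusted p = 1.04e-09), and Cdh1 fell by a log2 difference of -5.87 ± 0.51. Hamp, the hepcidin gene, rose by 3.24 ± 0.22 and Slc9a3 by 4.83 ± 0.88. Vegfb rose at least 394-fold, and Ephx2 and Serpinc1, at -7.65 ± 0.79, fell, which are genes of the crossing above. Nr0b1 fell at -2.81 ± 0.21, Star rose by 0.80 ± 0.08 and Cyp11b2 fell at -0.49 ± 0.13.

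Matrix genes fell, in a list where 2 of 33 members rose and 25 fell (median -0.90, -0.88 slide-blocked and -0.87 within slide, camera adjusted p = 4.67e-12, adjusted p = 0.382 with estimated correlation). Col3a1 was at -1.58 ± 0.22. Cell cycle genes fell, in a list where 2 of 43 members rose and 31 fell (median -0.80, -0.67 slide-blocked and -0.84 within slide, camera adjusted p = 1.21e-10, adjusted p = 0.396 with estimated correlation). Mcm3 was at -0.96 ± 0.14. Imprinted and growth genes fell as a list (2 of 13 higher, 9 lower, median -0.46, -0.47 slide-blocked and -0.57 within slide, camera adjusted p = 0.000533, adjusted p = 0.309 with estimated correlation). H19 was at -3.60 ± 0.34, while Igf1 rose by 2.10 ± 0.24. Markers of fat fell, in a list where 1 of 24 members rose and 15 fell (median -1.14, -1.42 slide-blocked and -1.90 within slide, camera adjusted p = 6.35e-06, adjusted p = 0.461 with estimated correlation). Fasn was at -1.87 ± 0.36. Beside it, the kidney and liver list had a median of -1.36, -1.65 with slide as a block and -3.12 within slide, where 3 of 21 members rose and 5 fell. The list was not called (camera adjusted p = 0.0756), and was called lower with that block (adjusted p = 0.0139). Without SHR replicate 2 at 3 weeks its median was -0.38 (adjusted p = 0.445), and without replicate 1 or 3 it was called (adjusted p = 0.00568 and 0.0218). All 8 blood genes fell (median -0.91, -0.74 slide-blocked and -0.86 within slide, camera adjusted p = 7.16e-06, adjusted p = 0.382 with estimated correlation). Antigen presentation genes rose, in a list where 16 of 35 members rose and 2 fell (median 0.37, 0.49 slide-blocked and 0.42 within slide, camera adjusted p = 3.62e-05, adjusted p = 0.391 with estimated correlation). Cholesterol genes rose as a list, where 13 of 29 members rose and 1 fell (median 0.38, 0.44 slide-blocked and 0.49 within slide, camera adjusted p = 9.7e-05, adjusted p = 0.382 with estimated correlation). Heat shock genes rose as a list (14 of 31 higher, 0 lower, median 0.26, 0.29 slide-blocked and 0.32 within slide, camera adjusted p = 0.0013, adjusted p = 0.391 with estimated correlation). Lymphocyte genes rose as a list (9 of 23 higher, 2 lower, median 0.46, 0.25 slide-blocked and 0.30 within slide, camera adjusted p = 0.0115, adjusted p = 0.391 with estimated correlation). Schwann cell genes fell as a list (2 of 19 higher, 6 lower, median -0.65, -0.86 slide-blocked and -0.60 within slide, camera adjusted p = 0.00669, adjusted p = 0.508 with estimated correlation). Immediate early genes fell as a list (1 of 27 higher, 10 lower, median -0.49, -0.44 slide-blocked and -0.43 within slide, camera adjusted p = 0.00698, adjusted p = 0.508 with estimated correlation). Endothelial genes fell as a list (1 of 23 higher, 6 lower, median -0.14, -0.10 slide-blocked and -0.07 within slide, camera adjusted p = 0.0115, adjusted p = 0.396 with estimated correlation). Mast cell genes fell as a list (1 of 18 higher, 6 lower, median -0.46, -0.63 slide-blocked and -0.74 within slide, camera adjusted p = 0.0213, adjusted p = 0.508 with estimated correlation). The genes linked to these strains by literature were called lower (1 of 18 higher, 6 lower, median -0.27, -0.45 slide-blocked and -0.49 within slide, camera adjusted p = 0.0215, adjusted p = 0.391 with estimated correlation).

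The limma count in SHR was 6096, 3151 up and 2945 down, with 1261 of at least 2-fold, and 5929 with slide as a block. The count was 3538 with these 6 arrays alone and 3859 without slide 5, left out after the data were seen.

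From 3 to 6 weeks in the arrays labelled SHRSP, Akr1c3 fell at least 538-fold to a level not well above background (limma adjusted p = 1.88e-09), Cdh1 fell by a log2 difference of -7.17 ± 0.51 and Sfrp4, a secreted antagonist of Wnt signals, of -5.45 ± 0.40. Slc9a3 rose by 4.95 ± 0.88 with 1 of 3 arrays well above background at 3 weeks. Vegfb fell at least 362-fold and Agtrap rose by 5.54 ± 0.16, both genes of the crossing. Cyp11b2 fell at -1.14 ± 0.13, and Star was at 0.17 ± 0.08, not past the threshold.

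Interferon genes rose, in a list where 21 of 36 members rose and 1 fell (median 0.70, 0.58 slide-blocked and 0.52 within slide, camera adjusted p = 8.72e-10, adjusted p = 0.713 with estimated correlation). Ifi27l2b was at 2.13 ± 0.21 and Eif2ak2 at 1.02 ± 0.13. Cell cycle genes fell, in a list where 0 of 43 members rose and 34 fell (median -0.87, -0.77 slide-blocked and -0.71 within slide, camera adjusted p = 2.55e-09, adjusted p = 0.713 with estimated correlation). Aurka was at -1.32 ± 0.12. In the matrix list 2 of 33 members rose and 28 fell (median -0.77, -0.77 slide-blocked and -0.90 within slide, camera adjusted p = 4.38e-07, adjusted p = 0.713 with estimated correlation). Ogn was at -0.98 ± 0.13. All 8 blood genes fell (median -0.77, -0.71 slide-blocked and -0.62 within slide, camera adjusted p = 0.000124, adjusted p = 0.713 with estimated correlation). Adipose markers fell as a list (1 of 24 higher, 13 lower, median -1.05, -1.16 slide-blocked and -1.23 within slide, camera adjusted p = 0.0211, lost with that block at adjusted p = 0.0574, adjusted p = 0.953 with estimated correlation). Elovl3 was at -2.28 ± 0.25. Mast cell and granulocyte genes fell as a list (1 of 18 higher, 9 lower, median -1.07, -1.05 slide-blocked and -1.27 within slide, camera adjusted p = 0.00629, lost with that block at adjusted p = 0.0574, adjusted p = 0.713 with estimated correlation). Endothelial genes were called lower (2 of 23 higher, 11 lower, median -0.34, -0.24 slide-blocked and -0.40 within slide, camera adjusted p = 0.0305, lost with that block at adjusted p = 0.0875, adjusted p = 0.713 with estimated correlation). Antigen presentation genes were called higher (10 of 35 higher, 2 lower, median 0.17, 0.25 slide-blocked and 0.20 within slide, camera adjusted p = 0.00201, adjusted p = 0.713 with estimated correlation).

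In limma 6034 genes changed with age in SHRSP, 2189 up and 3845 down, 1314 by at least 2-fold, and 7188 with slide as a block. With quantile normalization the share of rises among the calls was 48.3%, against 36.3%.

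Tests of the difference between strains in their change with age asked which genes followed age unequally. Against WKY, the age change in SHR was higher for Zfp597 by 3.18 ± 0.11 and Gfra1 by 3.07 ± 0.41, and lower for Fabp3, a fatty acid binding protein, by a log2 difference of -5.46 ± 0.89 (limma adjusted p = 0.00371). Cyp11b2 differed by 1.003 ± 0.18, Cyp11b1 by 0.64 ± 0.12 and Pnmt by 0.83 ± 0.17. All 3 genes fell with age in WKY, and of them only Cyp11b2 passed the threshold in SHR. Cd36 differed by -1.50 ± 0.21 in SHR and -1.31 ± 0.21 in SHRSP, where WKY rose and both others fell. In SHRSP against WKY, Uts2 differed by 5.67 ± 0.58 and Zbtb16, a glucocorticoid-responsive gene, by -4.64 ± 0.88. In SHRSP against SHR, Agtrap differed by 10.21 ± 0.22 and Star by -0.64 ± 0.12.

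The cell cycle list was called lower in its age change in SHR than in WKY (median -0.79, -0.66 slide-blocked, camera adjusted p = 1.46e-12, adjusted p = 0.513 with estimated correlation). The same held in SHRSP (median -0.85, -0.73 slide-blocked, camera adjusted p = 1.05e-09, adjusted p = 0.602 with estimated correlation). Of 43 members, 1 passed over all genes in SHR and 10 in SHRSP, or 23 and 30 adjusted over the list alone. The immediate early list was called lower in SHR (0 of 27 higher, 7 lower, median -1.03, -1.03 slide-blocked, camera adjusted p = 5.38e-09, adjusted p = 0.513 with estimated correlation). In SHRSP it was called lower as well (0 of 27 higher, 10 lower, median -1.23, -1.25 slide-blocked, camera adjusted p = 1.79e-06, adjusted p = 0.584 with estimated correlation). The adipose list was called lower in its age change in SHR (0 of 24 higher, 3 lower, median -1.22, -1.29 slide-blocked, camera adjusted p = 2.11e-09, adjusted p = 0.513 with estimated correlation). The adipose list was called lower in SHRSP too (0 of 24 higher, 1 lower, median -1.05, -0.89 slide-blocked, camera adjusted p = 0.00147, adjusted p = 0.633 with estimated correlation). The kidney and liver list was called lower in SHR, though its 1 member past the threshold, Slc22a6, was higher (1 of 21 higher, 0 lower, median -1.18, -1.63 slide-blocked, camera adjusted p = 0.0314, adjusted p = 0.625 with estimated correlation). Without SHR replicate 2 at 3 weeks its median was -0.051 (adjusted p = 0.273). The cholesterol list was called lower in its age change in SHRSP than in WKY (0 of 29 higher, 8 lower, median -0.46, -0.48 slide-blocked, camera adjusted p = 8.48e-07, adjusted p = 0.526 with estimated correlation). Insig1 was at -3.17 ± 0.30 and Idi1 at -2.14 ± 0.26. The interferon list was called higher in its age change in SHRSP than in SHR (7 of 36 higher, 1 lower, median 0.62, 0.70 slide-blocked, camera adjusted p = 2.04e-06, adjusted p = 0.864 with estimated correlation). Oasl was at 1.54 ± 0.30. The heat shock list was called lower (0 of 31 higher, 10 lower, median -0.27, -0.33 slide-blocked, camera adjusted p = 0.00253, adjusted p = 0.864 with estimated correlation). Hsph1 was at -1.52 ± 0.21.

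Limma called 1211 genes for SHR against WKY, 2100 for SHRSP against WKY and 2482 for SHRSP against SHR. With slide as a block the counts were 2622, 2845 and 4189. The first count fell to 519 without SHR replicate 2 at 3 weeks and 789 without replicate 3, to 590, 568 and 617 without WKY replicates 1, 2 and 3 at 3 weeks, and to 749 without SHR replicate 1 at 6 weeks. The second was 1306 without WKY replicate 2 at 3 weeks, and the third 1422 without slide 5, left out after the data were seen. Quantile normalization moved the share of higher calls from 37% to 50% for SHRSP against WKY and from 37.3% to 49.6% for SHRSP against SHR, where the median of all genes was -0.17, or -0.06 with quantile normalization.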

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

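The count of opposite signs, the nearest-array test and the ratio of counts for the first pattern were chosen after its values had been seen. The readings of the medulla test and of the splits of 12 arrays, and the count of each probe once in the second pattern, were also changed after their values were known. The other tests were set before their values were seen.

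The first pattern is that arrays labelled SHR and SHRSP differed in opposite directions at 3 and 6 weeks in genes of very large difference, such as Vegfb and Agtrap. Slide as a block left opposite signs in 19 of 23 genes of at least 4-fold at both ages, which argues against slides as the whole cause. A candidate explanation is an exchange of the SHR and SHRSP labels at one age, which goes with opposite signs in 22 of 25 such genes, with 6 of 6 arrays at 6 weeks correlating better with the other label's 3-week mean over 38 genes, each taken relative to WKY of its age, and with a ratio of 2.07, from 29 genes of at least 4-fold in the difference of the 2 ages against 14 in their sum. These 3 tests rest on overlapping genes, and without a fold threshold only 345 of 733 signs were opposite, or 69 of 100 at 2-fold. The labels do not conflict, and the age affected cannot be read from these files. A real strain difference that depends on age, or separate colonies, stays open and untested.

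The second pattern is that genes such as Oxnad1, Kynu and Vegfb were near background in one strain and bright in another. A sequence variant under a probe could give this. Of 47 other probes for genes called with at least 4-fold between a hypertensive strain and WKY, each counted once by its mean over the comparisons, 16 moved by under 50% of the named probe's change, against 2 of 11 for genes changed by age in WKY. The shares, 34% and 18.2%, differed by 15.9 points (Fisher's exact test, two-sided, p = 0.474), so that variants and expression cannot be told apart with so few probes. A variant carried by 1 strain does not give a change between the ages of that strain, as Vegfb showed under its labels.

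The third pattern is the higher chromaffin list in SHR and SHRSP. Its median stayed above 0 with slide as a block in 4 of 4 comparisons with WKY. This argues against slides, though in SHR at 3 weeks the block could not move the median. A larger share of medulla in the sampled glands would raise chromaffin genes by one factor, and of 124 member values 61.3% lay within 2 SE of the list median of their comparison, while 5 lay below 0 by more than 2 SE. The bound written beforehand, at least 50% within 2 SE, was met, but it was judged too loose once the value was known, since one factor would put nearly all values there. The values argue against a larger medulla share as the sole cause, and leave it open in part.

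The difference between strains in their change with age was past the threshold for 1211 genes in SHR against WKY, 2100 in SHRSP against WKY and 2482 in SHRSP against SHR. Among 100 splits of the same 12 arrays, the real one included, 4, 1 and 2 called as many. On genes complete on all arrays the real values were 1215, 2102 and 2473, and the highest other splits called 2651, 1914 and 5528. These splits mix groups that differ, which raised the median residual SD above the 0.184 of the real split in 99 of 99 others, to medians of 0.263, 0.263 and 0.254, so low counts in most of them could be foreseen and the shares do not decide whether chance gave the real counts. In the split that called 5528, each of the 4 groups held arrays of 1 age, so that its difference was one between ages. The 3 splits that outnumbered the real one for SHR against WKY each kept the 3 arrays of SHR at 6 weeks together. The counts with slide as a block were 2622, 2845 and 4189.

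The pairwise comparisons have 10 splits of 6 arrays each, too few for a share under 5%, and in each the real split alone, 1 of 10, called as many. SHR against WKY at 3 weeks called 3785, SHRSP against WKY 5442 and SHRSP against SHR 1645, with 0 as the highest other. At 6 weeks they called 6057, 4969 and 3108, with 3049, 1 and 1880 as the highest other. The values of 3049 and 1880 came from splits that follow slide 5, and the same comparisons with slide as a block called 7323 and 3953. The age comparisons called 2579, 6079 and 6008 in WKY, SHR and SHRSP, with 0, 0 and 1 as the highest other.

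Several genes changed unequally with age between strains, by the limma test of the difference. For SHR against WKY the log2 differences were 10.04 in Vegfb, 3.18 in Zfp597, 3.07 in Gfra1, -9.11 in Serpinc1, -5.70 in Aspg, -5.46 in Fabp3 and -5.36 in Ephx2. For SHRSP against WKY they were 8.99 in Serpinc1, 5.67 in Uts2, 5.54 in Agtrap, 2.73 in Ephx2, -10.37 in Vegfb, -4.64 in Zbtb16 and -4.47 in ste2. For SHRSP against SHR they were 18.10 in Serpinc1, 10.21 in Agtrap, 8.10 in Ephx2, -20.41 in Vegfb and -5.82 in Zfp597. Vegfb, Ephx2 and ste2 were well above background on no array of at least 1 group, so their values but Ephx2's 2.73 are fitted, not measured. Serpinc1 was well above it on 2 of 3 arrays of SHRSP at 3 weeks, and Aspg on 2 of 3 of SHR at 6 weeks. Of the adrenal genes named beforehand, Cyp11b1 differed by 0.64, Cyp11b2 by 1.003, Pnmt by 0.83 and Cd36 by -1.50 in SHR against WKY. Star differed by -0.41 and Cd36 by -1.31 in SHRSP against WKY, and Cyp11b2 by -0.65 and Star by -0.64 in SHRSP against SHR.

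Gene lists differed in their age change by camera with the preset correlation, and none with an estimated one, where the lowest adjusted p was 0.513 for SHR against WKY, 0.526 for SHRSP against WKY and 0.864 for SHRSP against SHR. The call was lost with slide as a block for steroid hormone synthesis (adjusted p = 0.0529) and the glucocorticoid list (adjusted p = 0.0723) in SHR against WKY, and for the glucocorticoid list in SHRSP against WKY (adjusted p = 0.058). For SHR against WKY the median was 0.25 for steroid hormone synthesis, 0.22 for antigen presentation and 0.21 for heat shock. It was -0.088 for renin-angiotensin and ion transport, -0.25 for the genes linked to these strains, -0.25 for interferon, -0.30 for blood and -1.22 for adipose tissue. It was -1.18 for kidney and liver, -0.23 for matrix, -0.79 for cell cycle, -1.03 for immediate early, -0.18 for glucocorticoid-responsive and -0.19 for fatty acid genes. For SHRSP against WKY the median was -0.46 for cholesterol, 0.23 for chromaffin, 0.37 for interferon, -0.28 for lymphocytes and -1.05 for adipose tissue. It was 0.29 for Schwann cells, -0.85 for cell cycle, -1.23 for immediate early, -0.29 for glucocorticoid-responsive, -0.15 for respiratory chain and -0.46 for fatty acid genes. For SHRSP against SHR it was -0.34 for cholesterol, 0.62 for interferon, 0.47 for Schwann cells and -0.27 for heat shock.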

How the results depend on the processing

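The fit without slide 5 was chosen after the data were seen. It leaves SHR at 6 weeks with 1 array, which is assumed to vary like the others. No called list or named gene turned its direction by its test under the alternatives that were run for them. The respiratory chain list in SHR against WKY at 6 weeks, not called before, was called the other way with quantile normalization, at a median of -0.099 against 0.06, and the cause was not tested. The median of the steroid list for age in WKY was -0.032, and 0.043 with slide as a block, where its call was lost. The majority of higher or lower calls turned with quantile normalization in 4 comparisons, both of SHRSP against WKY and those of SHR against WKY and SHRSP against SHR at 6 weeks. The near-even splits of SHR against WKY at 3 weeks and of age in SHR, 49.5% and 51.7% higher, crossed 50% under some other alternatives. Of 5880 repeats of list results, 5373 kept their side of the threshold, 250 lost the call, 112 of them with the estimated correlation, 256 gained it and 1 turned. Of 18589 repeats for named genes, 17329 kept it, 1239 lost it and 21 gained it.

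Counts moved by over 1.5 times are set against these. At 3 weeks they were 3797, 5462 and 1654 for SHR against WKY, SHRSP against WKY and SHRSP against SHR. At 6 weeks they were 6080, 4985 and 3118, and for age in WKY and SHR 2566 and 6096. Array weights gave 6292, 8431 and 3486 at 3 weeks, 5382 for SHRSP against SHR at 6 weeks and 10503 for age in SHR. They gave 2949 and 6078 for the age change in SHR against WKY (1211) and in SHRSP against SHR (2482). The slide block gave 2622 and 4189 for these, and no filter gave 773 for the first. The compared groups alone gave 1019 for SHRSP against SHR at 3 weeks and 2630, 2377 and 1233 at 6 weeks. They gave 1108 and 3538 for age in WKY and SHR, and 790 for the age change in SHR against WKY. At 3 weeks against WKY they gave more, 4240 and 6409. The median over genes of the replicate SD was 0.10 to 0.14 in the groups at 3 weeks and 0.16 to 0.20 at 6. No cause was tested. Without slide 5, and so with fewer arrays, the count was 3470 for SHR against WKY and 1364 for SHRSP against SHR at 6 weeks. It was 3859 for age in SHR and 1422 for the age change in SHRSP against SHR.

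Leaving out each array in turn gave 2639 to 3723, 3761 to 5169 and 892 to 1367 genes at 3 weeks, and 4699 to 5706, 3764 to 4681 and 2172 to 2951 at 6 weeks. Age gave 1440 to 2328 in WKY, 4394 to 6879 in SHR and 4570 to 5319 in SHRSP. The age changes gave 519 to 1212 for SHR against WKY, 1306 to 2116 for SHRSP against WKY (2100 with all arrays) and 1676 to 2787 for SHRSP against SHR. At 3 weeks SHRSP against SHR gave 892 without SHR replicate 2, 958 without SHRSP replicate 2 and 1046 without SHRSP replicate 3. Age in WKY gave 1490, 1558 and 1440 without WKY replicates 1, 2 and 3 at 3 weeks. The age change in SHR against WKY gave 590, 568 and 617 without these. It gave 519 and 789 without SHR replicates 2 and 3 at 3 weeks, and 749 without SHR replicate 1 at 6 weeks. The one in SHRSP against WKY gave 1306 without WKY replicate 2 at 3 weeks. The overlap of calls against WKY ran from 1806 to 2533 genes at 3 weeks and from 2508 to 2800 at 6 weeks. The correlation of fold changes ran from 0.652 to 0.718 and from 0.618 to 0.714.

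Replicate numbers gave no clear pairing of the arrays. Same-numbered arrays had a mean correlation of deviations of 0.017, with 13 of 45 pairs above 0.1, and 10 of 18 arrays correlated best with an array of their own number. Arrays of the same slide had a mean correlation of 0.229, with 15 of 24 pairs above 0.1, against -0.05 for arrays of other slides, which the fit without a slide block leaves out. A block for the replicate number gave counts of 3966, 5669 and 1784 at 3 weeks, 6266, 5203 and 3324 at 6 weeks, and 2799, 6365 and 6294 for age. It gave 1352, 2379 and 2750 for the age changes, all within 1.5 times.

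Signal over background limits dim genes to bounds. The median signal was 18.2 to 24.9 times the local background, and 18326 of the 20835 tested genes were well above background on all 18 arrays.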

Other observations

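The genes set out here for keeping one direction were picked after their values were seen. Clock genes differed between the strains in both directions, and the circadian list was called in none of the 12 comparisons, with or without slide as a block. It was called higher in SHRSP than in WKY at 3 weeks without the filter (camera adjusted p = 0.021), with the mean of probes (0.0296) or without WKY replicate 2 (0.036), and for age in WKY without replicate 1 at 6 weeks (0.0457). Npas2, a partner of Bmal1 in the activating arm of the clock, was lower than in WKY at -0.65 ± 0.14 in SHR and -2.84 ± 0.14 in SHRSP at 3 weeks. At 6 weeks it was at -2.56 ± 0.14 and -3.34 ± 0.14 (limma adjusted p = 1.79e-09 for the last). Bmal1 stood at -1.77 ± 0.16 and -2.61 ± 0.16 at 6 weeks. The repressor gene Cry1 was higher, at 1.60 ± 0.16 and 2.42 ± 0.16, and Per2 was at 1.55 ± 0.24 in SHR. At 6 weeks in SHRSP 8 of 19 members were higher and 5 lower than in WKY, with a median of 0.23 (camera adjusted p = 0.332). The hour at which glands were taken was not given in the sources used here.

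Muscle genes were the other list with no call in the 12 comparisons under the choices used for the report, with a median of -0.006 in SHRSP against WKY at 6 weeks (camera adjusted p = 0.747). For age in SHR the list was called lower with slide as a block, at a median of -0.30 (adjusted p = 0.0187), with all probes (0.0168) and without replicate 3 at 6 weeks (0.0496). For age in WKY it was called lower with all probes (0.0382) and without replicate 2 at 6 weeks (0.0384). Its member Atp2a1, a calcium pump gene, was lower than in WKY at -0.82 ± 0.21 and -1.49 ± 0.21 at 3 weeks. At 6 weeks it was at -1.42 ± 0.21 and -1.89 ± 0.21, with 2 of 3 arrays of SHR and of SHRSP well above background. Several genes were called the same way in all 4 comparisons with WKY, though none of their lists was. The interferon gene Ifi44l lay between -2.91 ± 0.13 and -2.36 ± 0.13, and Hdc, which makes histamine, between -1.44 ± 0.20 and -0.65 ± 0.20. The glutathione transferase gene Gstt3 ran from 1.09 ± 0.11 to 2.05 ± 0.11 and Nefh from 1.41 ± 0.15 to 1.96 ± 0.15. The replication gene Mcm7 ran from 0.69 ± 0.08 to 1.43 ± 0.08, although the cell cycle list was lower at 6 weeks. Slc12a3, a kidney transporter gene, ran from -1.45 ± 0.14 to -0.77 ± 0.14, while the kidney and liver list was called in none of the 4 comparisons with WKY on all arrays.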
